A study of Mus musculus with 8 samples.

How the data were processed

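RNA was measured in whole kidneys of mice 2 months old. The control group held 4 kidneys with the floxed Mta2 alleles (Mta2flx/flx), and the mutant group held 4 kidneys that also carried Six2Cre, a Cre recombinase driven by a gene of nephron progenitor cells. Libraries are named by group and by the number in their titles. Per the labels' protocols, total RNA was purified on columns with DNase treatment, ribosomal RNA was depleted, and barcoded libraries were made with the Ion Total RNA-seq kit. This keeps small structured RNAs as well as messenger RNA.

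The authors deposited 1 table of 23219 genes by 8 libraries, with group means, a ratio and a p-value. The file header gives gene symbols and library names and no unit. The deposited values were read as a coverage signal from their steps. Within a tolerance of 1e-06, 100% of values were whole multiples of the lowest value of their library, and each library summed to about 280 megabases. This alone would fit any whole-number count plus 1. Of the positive values, in steps, 0.0435% lay from 1 to 19, whereas read counts would hold many small numbers. A value was therefore read as the number of sequenced bases assigned to a gene, plus 1, scaled to a common total. No source states this unit, and all values in BPM and megabases rest on it. Bases are not reads, and read lengths are unknown, so the number of reads behind a value is unknown and no counting interval or floor is given. The signal was not divided by gene length by the authors, so levels of different genes are not comparable. Per the submitters' processing notes, bedtools and the mm10 build were used, with no version or role. The aligner, annotation, filters and treatment of strand and of reads with several matches are not given in the sources used here. The deposited ratio is the authors' mean of the mutant libraries divided by their mean of the control libraries. The deposited p-value equals an unadjusted 2-sided test with equal variances on the linear values, as recomputed here.

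Values were divided by 280, which gives bases per megabase assigned to genes (called BPM). Bases per library were recovered by dividing by the lowest value and ranged from 164 to 468 megabases. Genes with at least 1 BPM in 4 or more libraries were tested, which left 13060 genes. The test was limma 3.58.1 in R 4.3.3 on log2(BPM + 1), with a mean-variance trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2 scale with its pseudocount of 1 and understate changes of genes with low levels. The plan fixed before the data were examined had a branch for counts and a branch for normalized values. The unit turned out to be base coverage, so the second branch was used, with its limits read in BPM. The literal reading on the deposited scale is among the alternatives added later. Count-based tools were not used.

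Gene symbols were matched to GENCODE vM21 (GRCm38, the assembly also called mm10) for coordinates and gene classes, with older symbols looked up in a RefSeq table of the same assembly. Of the 23219 symbols, 23097 matched, and 43 named more than 1 locus. Coordinates are 1-based spans of whole genes. Small RNA genes were taken as the 701 genes of the classes for small nucleolar, small nuclear and micro RNA, RNase P and MRP RNA and the like. The small nucleolar RNA Snord17 had 32182 BPM on average, while its host gene Snx5 had 116, so intronic coverage was not credited to the host.

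There were 43 gene lists (cell types, pathways, complexes and sex-biased genes) fixed before the data were examined, and 623 of their 663 members matched the table. Lists with at least 3 tested members entered camera, which compares a list with all other genes, with a preset correlation of 0.01. Camera was repeated with the correlation estimated for each list, and fry was run as a second test. Counts of list members are given over all tested genes and adjusted over the list alone. List scores per library are mean log2 values of the members, compared by exact 2-sided permutation of the libraries.

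Named genes were chosen by a rule fixed beforehand. It takes up to 12 called genes in each direction with the largest changes, non-overlapping groups, a mean log2 value of at least 1 and a symbol that is not a predicted-gene name. Because fewer than 24 genes were called, it was filled with genes of the smallest unadjusted p. It adds the tested members of the NuRD list, Lats2, and in each list the called members or else the 2 members of smallest p. Other genes named were chosen after their values were seen or serve as usual markers.

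Alternatives fixed beforehand were no filter on low values, a filter of 5 BPM, array weights, a pseudocount of 0.1, leaving out the 20 most abundant genes, and leaving out each library. Alternatives chosen after seeing the data were leaving small RNA genes out of the totals, median scaling over other genes, quantile normalization, the small RNA share as a covariate, the deposited scale, robust variance shrinkage, and leaving out the 2 mutant libraries above 45% small RNA, with and without median scaling. Median scaling divided each library by its median ratio to the mean library over genes outside the small RNA class with a mean of at least 5 BPM. No columns of library values were left unused. The values of 1 member of the podocyte lists are not reported here.

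The fit was tested on simulated data for mutant against control with known changes. Of 98 tested genes changed by 2 log2 units, 43.9% were called, and of 94 changed by 4 log2 units, 89.4% were called, among 13012 genes tested. There were 8 false calls among 135, and 0 calls with no change simulated. Genes were drawn independently around a common mean profile with an assumed read length. The simulated libraries did not differ in small RNA share as the real ones do, so these rates need not hold for the real data.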

Results

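Whole-kidney RNA was compared between 4 control kidneys of the floxed Mta2 genotype and 4 mutant kidneys of the same genotype with Six2Cre. Mta2 encodes a subunit of NuRD, a complex that joins nucleosome remodelling with histone deacetylation, and Six2 marks the progenitors of the nephron epithelium. The series title places the deletion in nephron progenitors and names focal segmental glomerulosclerosis (FSGS), a scarring disease of the glomerulus, so the comparison asks how the kidney transcriptome differed at 2 months. The labels name 4 kidneys per genotype without stating outright that each came from its own animal, and p-values measure the spread between these samples.

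Sequenced bases assigned to genes came to 244, 181, 439 and 212 megabases in control libraries 3401, 3486, 3586 and 3587. They came to 164, 236, 295 and 468 megabases in mutant libraries 3382, 3387, 3487 and 3489. Small RNA genes, chiefly small nucleolar RNAs and the RNA subunits of RNase P and RNase MRP, took 29.4%, 34.3%, 15.9% and 24.1% of the bases in the controls. They took 26.4%, 48.0%, 52.6% and 25.9% in the mutants. The group means were 25.9% ± 7.90 and 38.2% ± 14.1 (SD, n = 4 each; exact permutation p = 0.229, 2-sided). Because all libraries were scaled to the same total, a larger small RNA share leaves fewer bases for other genes.

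**Figure D1:**
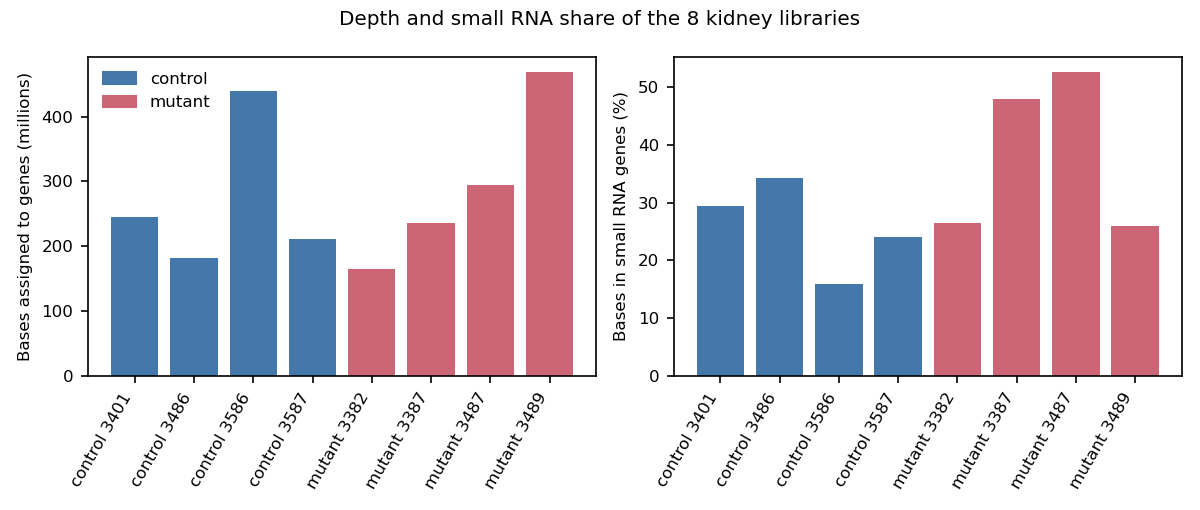
Bars give megabases assigned to genes (left) and the percentage of those bases in small RNA genes (right) for each of the 4 control and 4 mutant libraries. Mutant libraries 3387 and 3487 stand highest in small RNA share, at 48.0% and 52.6%.

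Mta2 itself (chromosome 19, 8941875 to 8952303, mm10) was measured at 51.1 ± 13.4 BPM (bases assigned to the gene per megabase assigned to all genes) in the controls and 37.2 ± 17.5 in the mutants (SD, n = 4 each). The values were 49.0, 35.1, 67.9 and 52.4 in the controls and 52.6, 33.1, 14.3 and 48.9 in the mutants. The log2 fold change was -0.56 (SE 0.40, 95% interval -1.40 to 0.28, limma adjusted p = 0.857), so no difference in Mta2 was detectable. Whole kidney contains cells outside the Six2 lineage. The values are per gene and not per exon, so coverage of undeleted exons may remain, which was not examined. This level is therefore a weak check of the labels. The estimate moved from -0.78 without mutant library 3382 to -0.17 without mutant library 3487. It was 0.06 with the small RNA share as a covariate.

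None of the 14 tested NuRD members passed the threshold over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. With the small RNA share as a covariate, chosen after seeing the data, Chd3 and Chd4 passed on the higher side (log2 fold changes 1.29 and 0.96, adjusted p of 0.0393 and 0.0219). The member with an unadjusted p under 0.05 in the main fit was Gatad2b. It was at 4.17 ± 2.07 in the controls and 1.44 ± 1.07 BPM in the mutants (SD, n = 4; log2 fold change -1.09, limma adjusted p = 0.766). The paralogs Mta1 and Mta3 had log2 fold changes of -0.28 and -0.39, the remodelling ATPases Chd3 and Chd4 0.29 and 0.03, and the deacetylases Hdac1 and Hdac2 0.22 and -0.23. The methyl-CpG binding proteins Mbd2 and Mbd3 were at -0.23 and -0.09, Gatad2a at -0.10, Rbbp4 and Rbbp7 at -0.18 and -0.50, and Cdk2ap1 at -0.08. Camera placed the list lower than other genes with an adjusted p of 0.840, although its median lay 0.02 above the median gene (adjusted p = 0.952 with an estimated correlation).

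The 13060 tested genes included 14 past the threshold, 10 higher and 4 lower in the mutants. Havcr1, the kidney injury molecule KIM-1 of damaged proximal tubule, rose from 52.0 ± 38.9 to 435 ± 155 BPM (SD, n = 4 each; log2 fold change 3.49, SE 0.56, limma adjusted p = 0.0103). Slc7a12, an amino acid transporter with higher levels in female than in male mouse kidney, rose from 4.29 ± 4.76 to 106 ± 43.4 (log2 fold change 4.67, SE 0.51, adjusted p = 7.6e-05). Clic6, of the chloride intracellular channel family, rose from 0.0686 ± 0.129 to 28.8 ± 12.7 (log2 fold change 4.69, SE 0.47, adjusted p = 2.42e-05). Timp1, an inhibitor of matrix metalloproteinases, rose from 0.0634 ± 0.117 to 7.15 ± 4.24 (log2 fold change 2.78, SE 0.48, adjusted p = 0.0184). All 4 mutant libraries lay above all 4 control libraries for each of these genes. Among the controls, Clic6 had coverage only in 3401 and Timp1 only in 3586.

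The other higher genes were H2-Q10, a non-classical class I histocompatibility gene (log2 fold change 3.32), the coagulation factor gene F10 (2.77), and Pla2g12b, of the secreted phospholipase family (2.53). Ptgds, which makes prostaglandin D (2.35), Rundc3a (2.34) and the small nucleolar RNA Snord15a (2.11) completed them, with limma adjusted p from 0.00424 for H2-Q10 to 0.0359 for Ptgds and Snord15a. H2-Q10 has close relatives in its gene family, and coverage that could be shared with them makes its value uncertain. Snord15a belongs to the small RNA class. Under median scaling its log2 fold change was 2.37 with an adjusted p of 0.0725.

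Dnase1, the secreted nuclease that degrades extracellular DNA, fell from 660 ± 124 to 79.6 ± 18.3 BPM (SD, n = 4 each; log2 fold change -3.05, SE 0.30, limma adjusted p = 2.42e-05). Anxa13, an epithelial annexin, fell from 12.1 ± 6.83 to 1.00 ± 0.762 (log2 fold change -2.66, SE 0.50, adjusted p = 0.0359). The alpha-globin genes Hba-a1 and Hba-a2 fell by 2.07 and 1.86 on the log2 scale, with adjusted p of 0.00765 and 0.0164. These copies are nearly identical, so the division of coverage between them is uncertain.

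In mm10 the higher genes lie at chromosome 16, 92485736 to 92541243 (Clic6), chromosome 3, 14480697 to 14505830 (Slc7a12), chromosome 11, 46735080 to 46779578 (Havcr1), chromosome 17, 35470089 to 35474563 (H2-Q10) and chromosome X, 20870166 to 20874735 (Timp1). F10 lies at chromosome 8, 13037308 to 13056676, Pla2g12b at chromosome 10, 59403660 to 59421976, and Ptgds at chromosome 2, 25466709 to 25470046. Rundc3a lies at chromosome 11, 102393403 to 102402555, and Snord15a at chromosome 7, 99482785 to 99482932. Of the lower genes, Dnase1 lies at chromosome 16, 4036942 to 4040024, and Anxa13 at chromosome 15, 58341471 to 58389244. Hba-a1 and Hba-a2 are neighbours on chromosome 11, at 32283511 to 32284465 and 32296489 to 32297298.

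**Figure D2:**
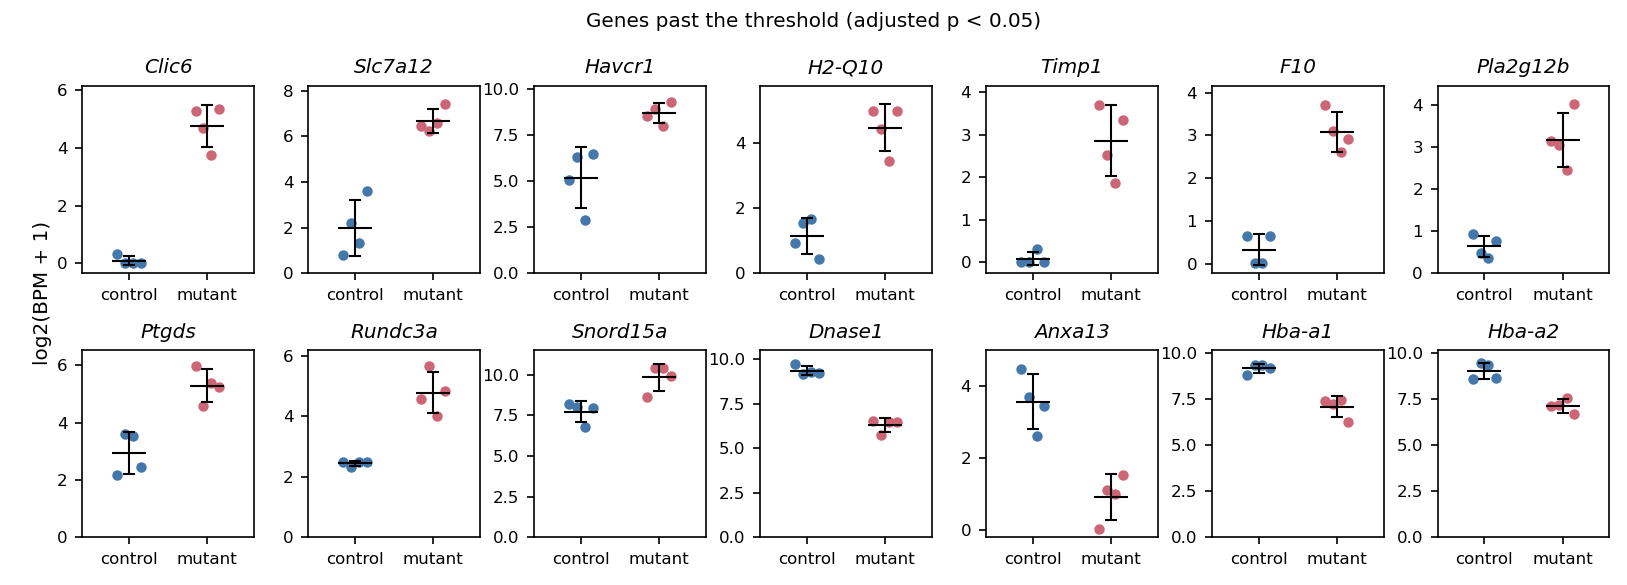
Points are single libraries, 4 control and 4 mutant, for the 14 genes past the threshold, on a log2 axis of BPM plus 1. The horizontal line and bars give mean and SD, and in each panel the 4 mutant libraries do not overlap the 4 controls.

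The genes of smallest unadjusted p that filled the naming rule all stayed short of the threshold. Nags, the enzyme that makes the activator of the urea cycle, had no coverage in any control and was at 4.16 ± 1.73 BPM in the mutants (SD, n = 4; limma adjusted p = 0.0536). Its control value of 0.00415 ± 0.00138 is only the added base scaled by library depth. Abp1, diamine oxidase, had a log2 fold change of 2.89 (adjusted p = 0.0586). Eci3 was at 124 ± 34.8 and 39.2 ± 14.6 and Afmid at 109 ± 27.4 and 35.8 ± 6.96, each with an adjusted p of 0.0683, and Upb1 had a log2 fold change of -1.53 (0.0704). Cyp2a4, Isoc2a, Abhd14a, Hao2 and Isoc2b had log2 fold changes of -1.47, -1.59, -1.35, -1.66 and -1.76 with adjusted p from 0.0731 to 0.120. Cyp2a4 and the pair Isoc2a and Isoc2b have close paralogs, so their values are uncertain.

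The median tested gene had a log2 fold change of -0.23, and 827 genes had an unadjusted p under 0.05. This median rested on single libraries. It was -0.03 without mutant 3487, -0.12 without mutant 3387 and -0.10 without control 3586, against -0.38 without mutant 3382, -0.37 without mutant 3489 and -0.35 without control 3486. It was 0.23 without both mutants above 45% small RNA, an alternative chosen after seeing the data. For 560 genes (4.29%) the groups did not overlap, against 2.86% by chance. Median scaling, chosen after seeing the data, brought the median gene to 0.00. It called 63 genes, 53 higher and 10 lower (84.1% higher, against 71.4% for the authors' scaling), and these included 9 of the 10 higher and 3 of the 4 lower genes. The count of 14 fell to 8 without control 3401, 8 without control 3587, 5 without mutant 3387 and 5 without mutant 3489. It rose to 37 without control 3486 and 40 without mutant 3487. Clic6, F10, Timp1 and Pla2g12b were under 1 BPM in all controls, so the filter took them out of the test whenever a mutant library was left out, and the counts without a mutant library exclude them. Slc7a12 and Dnase1 stayed past the threshold in all 21 alternatives. Havcr1 had an adjusted p of 0.0662 without mutant 3387, and Timp1 of 0.0781 and 0.0960 without controls 3401 and 3587. Pla2g12b lost its call without controls 3401, 3586 or 3587 (adjusted p of 0.0825, 0.0552 and 0.127). Hba-a2 lost its call without mutants 3387 or 3489 (0.0885 and 0.0719). Ptgds, Rundc3a, Snord15a and Anxa13 each lost it without at least 4 of the single libraries, controls 3401 and 3587 and mutants 3387 and 3489 among them. The largest adjusted p of these 4 genes without any of those 4 libraries were 0.202, 0.206, 0.209 and 0.204.

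Of the 36 lists with enough tested members, camera placed 19 past the threshold, 12 higher and 7 lower than other genes. With an estimated correlation, 1 list, the female-biased kidney genes, stayed past it. The second set test, fry, passed the erythrocyte list (adjusted p = 0.0336) and the female-biased list (0.0347), and the next smallest adjusted p was 0.345, for oxidative phosphorylation. List medians are given below relative to the median tested gene unless stated otherwise, and log2 fold changes of single genes are not. Of the 13060 tested genes, 3715 had a positive log2 fold change, so negative signs were the more common background for the lists.

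Genes of macrophages and dendritic cells were higher in the mutants, with all 18 tested members at a positive log2 fold change and a list median 1.16 above the median gene (camera adjusted p = 3.69e-15). The adjusted p = 0.441 with an estimated correlation. No member passed over all genes, and 3 passed adjusted over the list alone, namely the lysozyme gene Lyz2, the lipopolysaccharide co-receptor Cd14 and the complement component C1qb. Without single libraries the latter count ranged from 1 (control 3401, 3586 or 3587, mutant 3382 or 3489) to 13 (mutant 3487). Lyz2 was at 71.1 ± 21.5 and 465 ± 436 BPM, and Cd14 at 12.2 ± 3.48 and 35.6 ± 19.5 (SD, n = 4 each). The mutant libraries varied widely. Lyz2 was at 1057, 165, 110 and 529 in mutants 3382, 3387, 3487 and 3489, and the 2 lower values came from the libraries with the highest small RNA share. On the list score, 2 of 4 mutants lay above all controls and 1 below them (exact permutation p = 0.286), and after median scaling 4 of 4 lay above them.

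The tubular injury list was higher by camera, with a median 0.94 above the median gene (camera adjusted p = 6.49e-14, and adjusted p = 0.441 with an estimated correlation). Of its 22 tested members, Havcr1 passed over all genes, and Havcr1, C3 and Vcam1 passed adjusted over the list alone. Complement genes were higher by the same test, with a list median 0.28 above the median gene (camera adjusted p = 3.51e-06, and adjusted p = 0.441 with an estimated correlation). Among 11 members none passed over all genes, and 3 passed adjusted over the list alone. They were C3, the central complement protein (9.53 ± 3.20 and 106 ± 93.3 BPM, n = 4), C4b (7.08 ± 2.94 and 74.7 ± 80.0) and Cfi (1.99 ± 0.109 and 27.0 ± 22.1). The list of chemokines, cytokines and NF-kB had a median 0.86 above the median gene (camera adjusted p = 1.07e-07, and adjusted p = 0.441 with an estimated correlation). None of its 11 members passed over all genes, and 2 passed adjusted over the list alone, the monocyte chemokine Ccl2 (0.661 ± 0.321 and 8.83 ± 7.49) and the adhesion molecule Vcam1 (11.5 ± 4.94 and 62.4 ± 51.4). C3 and Vcam1 stand in more than 1 of these lists. On the list scores, mutant 3487 lay below all controls for the tubular injury, complement and chemokine lists. Above all controls lay 3, 3 and 2 of 4 mutants. The exact permutation p was 0.143, 0.171 and 0.286, and 0.629 for each after adjustment over the lists. Over the list alone, 11 injury genes passed without mutant 3487. Over all genes, the injury count was 0 without mutant 3387, 2 without control 3586 and 3 without mutant 3487, and the complement count was 1 without control 3586 and 3 without mutant 3487. Ccl2 was under 1 BPM in all controls and was not tested when a mutant library was left out. Over the list alone, Vcam1 was therefore the only chemokine list call open to loss there, and the count was 0 without mutants 3382 or 3489 and 1 without mutant 3387. It was 1 without control 3587.

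Matrix and fibroblast genes were higher by camera, with 26 of 30 members at a positive log2 fold change and a median 0.82 above the median gene (camera adjusted p = 6.49e-14, and adjusted p = 0.441 with an estimated correlation). Timp1 passed over all genes and adjusted over the list alone. Timp1 was under 1 BPM in all controls and left the test through the filter whenever a mutant library was left out. Among the 29 members still tested, the counts over all genes and over the list alone were 2 and 14 without mutant 3487 and 0 without the other mutants. The count over all genes was 0 without controls 3401 or 3587, where Timp1 was tested. On the matrix list score, 3 of 4 mutants lay above all controls and mutant 3487 lay below them. The exact permutation p was 0.314, and 0.629 after adjustment over the lists. The collagen gene Col1a1 was at 15.2 ± 4.63 and 61.1 ± 58.2 BPM (SD, n = 4; limma adjusted p = 0.638), with 144, 37.4, 9.78 and 53.2 in mutants 3382, 3387, 3487 and 3489. Cell cycle genes had a median 0.74 above the median gene (camera adjusted p = 3.37e-06), and parietal epithelium genes 0.96 (camera adjusted p = 0.000221). Both had an adjusted p = 0.441 with an estimated correlation, and 0 of their 13 and 7 members passed over all genes or over the list alone. Top2a was at 1.81 ± 1.36 and 4.67 ± 2.29, Cdk1 at 2.34 ± 0.947 and 6.16 ± 3.12, Krt19 at 3.29 ± 2.16 and 10.2 ± 8.32, and Krt8 at 79.9 ± 8.94 and 148 ± 78.6.

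**Figure D3:**
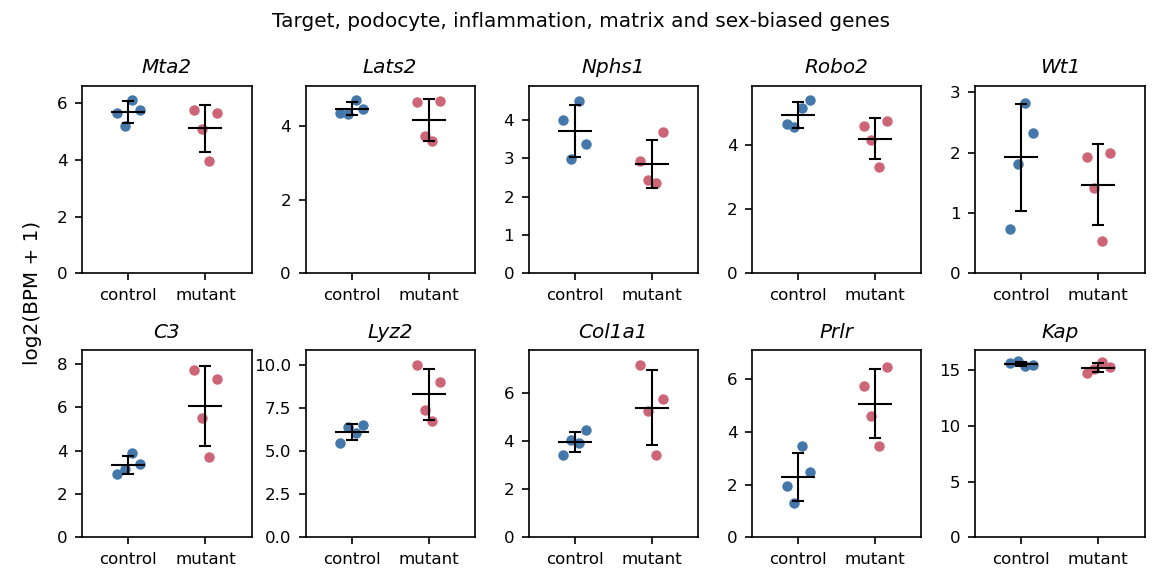
Points are single libraries, with mean and SD as line and bars, on a log2 axis of BPM plus 1, for Mta2, Lats2, podocyte genes, inflammation and matrix genes and sex-biased genes. Mta2, Nphs1 and Robo2 overlap between the groups, while C3, Lyz2 and Col1a1 spread more among the 4 mutants than among the 4 controls.

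Marker lists of 3 tubule segments lay lower in the mutants. Those of principal cells (camera adjusted p = 0.707, median 0.21 above the median gene) and intercalated cells (0.284) did not pass. The intercalated median was -0.23 relative to the median gene, close to that of the proximal tubule list, with 10 of 11 members negative. The proximal tubule list had 29 of 32 members at a negative log2 fold change and a median of -0.24 relative to the median gene (camera adjusted p = 0.000389, and adjusted p = 0.778 with an estimated correlation). None passed over all genes or adjusted over the list alone. Napsa was at 2436 ± 499 and 1228 ± 328 BPM (SD, n = 4; limma adjusted p = 0.415) and Acsm2 at 1851 ± 433 and 983 ± 284 (0.531). The distal convoluted tubule list had a median of -0.42 relative to the median gene (camera adjusted p = 0.000919, and adjusted p = 0.498 with an estimated correlation). Of its 10 members, 0 passed over all genes and 2 adjusted over the list alone, Pvalb (96.9 ± 24.3 and 36.0 ± 17.0) and the sodium-calcium exchanger Slc8a1 (292 ± 45.3 and 157 ± 40.7). The latter count was 4 without control 3486 and 1 without controls 3401 or 3586 or mutants 3387, 3487 or 3489.

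The thick ascending limb list was at -0.27 relative to the median gene (camera adjusted p = 0.0246, and adjusted p = 0.778 with an estimated correlation), with 0 of 12 members past either threshold. Egf was at 1004 ± 512 and 479 ± 165 BPM, and Cldn10 at 352 ± 53.4 and 215 ± 30.0 (SD, n = 4). This list lost its call in 9 of 21 alternatives, among them the filter of 5 BPM (adjusted p = 0.0770), array weights (0.0641), median scaling (0.0503) and leaving out control 3586 (0.0686) or mutant 3487 (0.168). Nuclear genes of oxidative phosphorylation were lower, with 27 of 27 members at a negative log2 fold change and a median of -0.34 relative to the median gene (camera adjusted p = 2.54e-07, and adjusted p = 0.441 with an estimated correlation). None passed over all genes and 1, Cox6c (log2 fold change -1.57, limma adjusted p = 0.225), adjusted over the list alone. That count was 7 without mutant 3382, 2 without control 3586 and 0 without any other single library (controls 3401, 3486 and 3587, mutants 3387, 3487 and 3489). On the list score of oxidative phosphorylation, 3 of 4 mutants lay below all controls (exact permutation p = 0.0571). After median scaling 1 of 4 did (exact permutation p = 0.229). Endothelial genes had a median of -0.31 relative to the median gene (camera adjusted p = 0.0178, and adjusted p = 0.782 with an estimated correlation). None of the 17 passed either threshold, and the list lost its call without control 3586 (0.0953). Kdr was at 84.6 ± 26.0 and 41.7 ± 18.6, and Eng at 68.3 ± 18.5 and 35.8 ± 13.4.

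Red cell transcripts were lower in the mutants. All 6 tested erythrocyte genes had a negative log2 fold change, with a list median of -1.40 relative to the median gene (camera adjusted p = 5.1e-10, and adjusted p = 0.0815 with an estimated correlation). Hba-a1 and Hba-a2 passed over all genes (1 of them without mutant 3387 or 3489), and 5 members passed adjusted over the list alone, with Alas2, Beta-s and Hbb-b2 beside them. Hba-a1 was at 579 ± 98.0 and 142 ± 45.2 BPM, and Alas2, the heme synthesis enzyme of red cells, at 30.1 ± 14.5 and 8.43 ± 3.58 (SD, n = 4). Beta-s and Hbb-b2 are globin copies with an uncertain division of coverage. On the list score, 4 of 4 mutants lay below all controls (exact permutation p = 0.0286, the smallest that 4 against 4 allows), and after median scaling 3 of 4 did (exact p = 0.0571). Adjusted over the lists, these exact p-values were 0.514 and 0.176.

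Female-biased kidney genes rose in the mutants. All 3 members passed adjusted over the list alone, and Slc7a12 over all genes (2 members without control 3586, 3 without mutant 3487). The prolactin receptor Prlr was at 4.73 ± 3.73 and 42.5 ± 33.4 BPM (SD, n = 4; limma adjusted p = 0.0694), and the fatty acid hydroxylase Cyp4a14 at 4.95 ± 3.32 and 23.5 ± 15.7 (0.477). The list lay 2.98 above the median gene (camera adjusted p = 6.49e-14, and adjusted p = 0.0455 with an estimated correlation). On the list score, 4 of 4 mutants lay above all controls (exact permutation p = 0.0286, and 0.514 after adjustment over 36 lists). The 9 male-biased genes had a median of -0.21 relative to the median gene (camera adjusted p = 0.0311, and adjusted p = 0.498 with an estimated correlation), with 0 past either threshold. Cyp7b1 was at 101 ± 32.0 and 47.7 ± 35.8, and Timd2 had a log2 fold change of -0.89. This call was lost in 8 of 21 alternatives, among them the filter of 5 BPM (0.0647), median scaling (0.134) and leaving out control 3401 (0.210), control 3486 (0.132) or mutant 3382 (0.729). All 8 libraries expressed Y-linked genes, whose sum ranged from 65.2 to 139 BPM, and Xist was at most 1.57. The Y-linked list gave a camera adjusted p of 0.529 with 0 of 4 members past either threshold, Eif2s3y at 25.5 ± 6.45 and 18.4 ± 11.9 among them. The X-inactivation list had 0 tested members.

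Podocyte genes, which the FSGS in the series title would bring to mind first, did not pass. Of 35 tested podocyte genes 0 passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.659). Nphs1, the slit diaphragm protein nephrin, was at 13.2 ± 6.55 and 6.79 ± 3.67 BPM (SD, n = 4; log2 fold change -0.86, 95% interval -1.84 to 0.12, limma adjusted p = 0.828). Robo2, a receptor of the slit diaphragm, was at 30.9 ± 9.04 and 18.8 ± 7.60 (log2 fold change -0.75, limma adjusted p = 0.826). The 35 tested genes of monogenic podocytopathies gave 0 past either threshold (camera adjusted p = 0.707), with Anln at 1.61 ± 1.19 and 5.14 ± 5.15. The 8 mesangial and juxtaglomerular genes gave 0 (camera adjusted p = 0.897, on the higher side), with Ren1 at 12.3 ± 9.87 and 4.57 ± 2.43 and Cspg4 at 13.7 ± 5.92 and 22.9 ± 8.46. The median log2 fold change of this list was -0.23, which is -0.0022 relative to the median gene.

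Lats2, a kinase of the Hippo pathway, was at 21.4 ± 2.83 and 18.1 ± 7.35 BPM (SD, n = 4; log2 fold change -0.31, 95% interval -1.12 to 0.51, limma adjusted p = 0.906). Its gene lies at chromosome 14, 57689662 to 57758388. None of the 26 tested Hippo pathway and YAP target genes passed over all genes or over the list alone (camera adjusted p = 0.529, but 0.0223 on the higher side with the small RNA share as covariate), with Mob1b at 34.7 ± 10.6 and 21.8 ± 11.6 and Amotl2 at 48.6 ± 33.0 and 28.5 ± 18.1. Of 11 tested nephron progenitor and early nephron genes 0 passed (camera adjusted p = 0.707), with Crym at a log2 fold change of -0.98 and Meox1 at 10.5 ± 3.75 and 5.40 ± 2.71. Of 6 fetal and imprinted growth genes 0 passed over all genes and 2 adjusted over the list alone, Igf2 (1.65 ± 0.697 and 0.0579 ± 0.107) and Peg3 (23.0 ± 10.2 and 8.81 ± 1.43), with a camera adjusted p of 0.677. Camera placed this list on the lower side while its median lay 0.02 above the median gene. Igf2 reached 1 BPM only in the 4 controls and was not tested when one of them was left out. Over the list alone, 0 of the 6 members passed without mutants 3382, 3387 or 3489. Of the 5 left without a control, 0 passed without 3401, 3586 or 3587 and 1 without 3486.

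Interferon response, T cell, smooth muscle and adipocyte lists were higher by camera, with adjusted p of 0.00632, 0.0354, 0.0208 and 0.0311. They had adjusted p = 0.782, 0.521, 0.441 and 0.441 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone, and single libraries ended each call. Calls were lost in 2 of 21 alternatives for interferon response, 6 of 21 for smooth muscle, 12 of 19 for T cells and 10 of 18 for adipocytes. Under median scaling the smooth muscle, T cell and adipocyte lists had adjusted p of 0.0503, 0.0545 and 0.133. The interferon call was lost without control 3401 (0.103) or mutant 3382 (0.145), and the smooth muscle call without mutant 3387 (0.132). The T cell call was lost without control 3401, 3586 or 3587 (0.112, 0.167 and 0.108) or mutant 3382, 3487 or 3489 (0.483, 0.130 and 0.0501). The adipocyte call was lost without control 3401 or 3587 (0.138 and 0.301) or mutant 3387 or 3487 (0.132 and 0.611). Gbp2 was at 10.1 ± 1.49 and 18.2 ± 10.2 BPM, Cd4 at 1.05 ± 1.56 and 3.03 ± 2.39, Tagln at 53.2 ± 16.9 and 95.4 ± 53.1, and Plin4 at 1.82 ± 2.47 and 3.17 ± 2.05 (SD, n = 4 each).

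The remaining lists did not pass camera and had 0 members past the threshold over all genes. Beside principal and intercalated cells, camera adjusted p was 0.529 for fatty acid oxidation, 0.120 for cholesterol synthesis and 0.135 for p53 and senescence. It was 0.707 for the unfolded protein response, 0.572 for renin-angiotensin, 0.290 for immediate early and heat shock genes and 0.817 for urothelium. Adjusted over the list alone, 1 member of the cholesterol list, Idi1 (82.3 ± 15.7 and 36.8 ± 16.1 BPM), and 0 of the other lists passed. Idi1 no longer passed without controls 3401, 3486 or 3587 or mutants 3382, 3387 or 3487, and 2 members passed without mutant 3489. The p53 list passed camera without mutant 3387 (0.0431), and the cholesterol list without mutant 3489 (0.0158). The immediate early list had a median log2 fold change of 0.12 (0.35 relative to the median gene) and a mean of -0.00152. Aqp4 was at 50.1 ± 24.8 and 19.8 ± 15.1, Slc26a4 at 30.3 ± 9.22 and 16.6 ± 5.73, Agt at 44.7 ± 26.0 and 97.1 ± 45.7, Acadm at 620 ± 55.8 and 418 ± 151, and Gdf15 at 2.88 ± 2.03 and 7.08 ± 5.94. Herpud1 was at 419 ± 142 and 292 ± 97.6, Dusp1 at 42.0 ± 24.7 and 22.8 ± 12.9, and Upk3b at 2.45 ± 0.999 and 1.06 ± 1.83.

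Lists with fewer than 3 tested members entered no set test. Igj, the joining chain of secreted antibody, was at 9.94 ± 5.79 and 70.9 ± 49.1 BPM (SD, n = 4; limma adjusted p = 0.0975) and was 1 of 2 tested B cell and plasma cell genes, which passed adjusted over the list alone. The adrenal list had 1 tested member, Fdx1 (52.8 ± 6.60 and 30.9 ± 4.93; limma adjusted p = 0.722 over all genes). With 1 member, adjustment over the list leaves the p-value unchanged. It was under the threshold, but not without control 3401, control 3587 or mutant 3387. The lists for skeletal muscle and liver (Serpina1a at 11.8 ± 12.6 and 20.6 ± 6.70), neutrophils (S100a8 at 0.797 ± 0.536 and 2.50 ± 2.83) and residual structural RNA (Rmrp at 60139 ± 23433 and 39867 ± 15223) had 2 tested members each and 0 past either threshold. Mitochondrially encoded genes had 0 tested members.

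**Figure D4:**
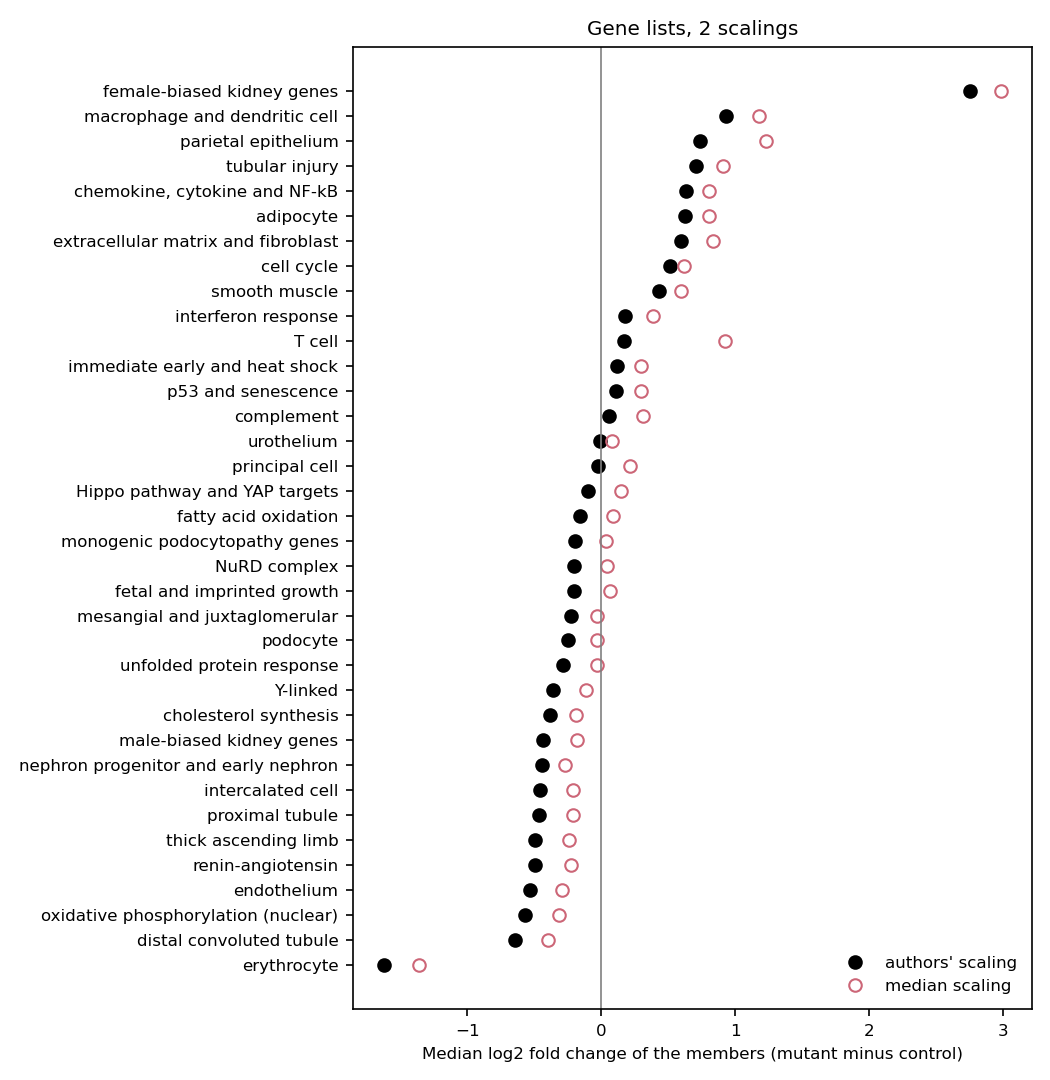
Points give the median log2 fold change of each list's tested members, mutant minus control, with the authors' scaling (filled) and median scaling (open), for the 36 lists that entered the set test. The female-biased list lies highest under both scalings, at 2.75 and 2.99, and the erythrocyte list lowest, at -1.62 and -1.36.

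The authors' deposited table gives an unadjusted p under 0.05 for 1046 genes, 217 with a ratio above 1 and 829 below 1. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 0 genes under 0.05, with a smallest adjusted value of 0.459. The authors' deposited table gives Mta2 a ratio of 0.729 (p = 0.255), Havcr1 8.37 (p = 0.00301) and Slc7a12 24.7 (p = 0.00350). It gives Dnase1 a ratio of 0.121 (p = 8.96e-05) and Nphs1 0.514 (p = 0.138), again as values of the authors' deposited table.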

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

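No test in this part was chosen after the result was seen. A fixed rule for a library far from its group was run on 82 groups of 4 libraries, of which 5 stood out. Chance alone gives 4.1. In log2(BPM + 1), control 3401 stood apart for Clic6, at 0.336 against a nearest control of 0.00794. Control 3586 stood apart for Timp1, at 0.309 against 0.00794, and both of these are levels near 0 coverage. Control 3486 was lowest for Rundc3a, at 2.31 against 2.48. Control 3586 was lowest for Snord15a, at 6.75 against 7.97, and is also the library with the smallest share of small RNA (15.9%). Mutant 3387 was lowest for Dnase1, at 5.74 against 6.45.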

How the results depend on the processing

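The alternatives on small RNAs, scaling, shrinkage and the 2 mutant libraries were chosen after the result was seen. The 14 called genes (10 higher, 4 lower) were the result most open to processing. Alternatives fixed beforehand called 4 genes (3 and 1) with no filter, 9 (6 and 3) with a filter of 5 BPM, 73 (47 and 26) with array weights, 9 (6 and 3) with a pseudocount of 0.1 and 45 (34 and 11) without the 20 most abundant genes. Leaving out 1 library gave 5 to 40 genes, 3 to 33 higher and 2 to 13 lower. Alternatives chosen after seeing the data called 59 (49 and 10) without small RNA genes, 63 (53 and 10) with median scaling, 69 (57 and 12) with quantile normalization and 490 (417 and 73) with the small RNA share as covariate. They called 2 (1 and 1) on the deposited scale and 14 with robust shrinkage. Without both mutant libraries above 45% small RNA, 51 genes were called (44 and 7), and 45 (35 and 10) with median scaling as well. The causes of these differences were not tested.

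Set tests past the threshold numbered 19, and 1 with an estimated correlation. The other 21 alternatives gave from 14 to 22. Calls for cell cycle, chemokines, complement, distal convoluted tubule, erythrocyte, matrix, female-biased, macrophage, oxidative phosphorylation, parietal epithelium, proximal tubule and tubular injury lists held in all 21. The other calls were lost in 1 alternative for endothelium, 2 for interferon response, 6 for smooth muscle, 8 for male-biased genes and 9 for the thick ascending limb, and in 12 of 19 for T cells and 10 of 18 for adipocytes. Beyond those named with the lists, the thick ascending limb was at 0.0663 with quantile normalization and 0.374 with the small RNA share as covariate. Among alternatives fixed beforehand, the T cell list was at 0.0505 with a pseudocount of 0.1. The adipocyte list was at 0.155 with no filter and 0.0824 without the 20 most abundant genes, where the male-biased list was at 0.0750. In 2 cases a list past the threshold in 1 of the 2 settings compared lay on the other side in the other. The adipocyte list went lower, at an adjusted p of 0.599, with the small RNA share as covariate, and the urothelium list went lower, at 0.0484, without both high small RNA mutants. The cause was not tested. Lists short of the threshold passed it in 12 comparisons. They were the Hippo list (0.0223) and the monogenic podocytopathy list (0.0270) with the small RNA share as covariate, and the Hippo list (0.0499) with median scaling without both high small RNA mutants. The p53 list passed in 4 alternatives, with 0.0140 as its smallest adjusted p, the immediate early list in 3 (0.0284) and the cholesterol list in 2 (0.0117). Mta2 stayed short of the threshold in all 21 alternatives, from -0.78 to 0.06 on the log2 scale. Among 2173 comparisons of named genes 64 lost a call and 131 gained one, and none had a call on one side and the opposite sign on the other. Fold changes short of the threshold did turn sign, for Mta2 in 2 alternatives, Mbd3 in 12 and Gatad2a in 10.

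DESeq2, RLE scaling and svaseq were not run because they need counts. The Y-linked covariate was not run because its condition, a difference between libraries in sex, was not met. Depth in reads is unknown, so the precision of low genes such as Clic6 or Timp1 in the controls could not be given from counting.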

Other observations

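The tests below were chosen after the results were seen, apart from the counts of splits for gene lists.

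Under median scaling, 63 genes passed, with limma adjusted p under the threshold, and the genes below are among them. Mdk, the growth factor midkine, rose from 25.9 ± 6.09 to 86.3 ± 11.2 BPM (SD, n = 4; adjusted p = 0.00211), the chemokine gene Ccl9 from 5.94 ± 3.28 to 32.9 ± 10.9 (0.00376), and the laminin gene Lama3 from 9.34 ± 2.52 to 29.4 ± 1.37 (0.0103). The lipid desaturase Scd1 rose from 40.5 ± 27.5 to 327 ± 184 (0.0125) and the carboxylesterase Ces1g from 6.56 ± 3.41 to 46.3 ± 15.7 (0.00211). Angiotensinogen, Agt, rose from 37.5 ± 15.5 to 96.6 ± 19.8 (0.0429), Prlr from 3.84 ± 2.27 to 38.9 ± 21.5 (0.00270), and the collagen gene Col3a1 from 80.9 ± 14.7 to 316 ± 206 (0.0473). Upb1 fell from 130 ± 26.3 to 52.5 ± 7.59 (0.0157), and the coagulation subunit F13b from 107 ± 17.8 to 49.9 ± 2.71 (0.0281). These genes were chosen after their values were seen. With the authors' scaling none of them passed. There the limma adjusted p was 0.631 for Agt, 0.461 for Col3a1, 0.287 for Lama3, 0.167 for Mdk and F13b and 0.102 for Scd1. It was 0.0768 for Ccl9, 0.0704 for Upb1, 0.0694 for Prlr and 0.0659 for Ces1g.

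At the level of libraries, 7 list scores lay above all controls in 4 of 4 mutants after median scaling. They were cell cycle, chemokines, complement, matrix, female-biased, macrophage and tubular injury genes. The scores of the distal convoluted tubule, thick ascending limb and endothelium lay below all controls in 4 of 4. Some margins were narrow. The matrix score was 4.294 in mutant 3487 against 4.291 in control 3486, and the endothelial score 4.501 in mutant 3387 against 4.512 in control 3401. Each of these separated lists gave an exact permutation p of 0.0286, the smallest that 4 against 4 allows, and 0.106 after adjustment over 37 lists. With the authors' scaling, 1 list lay above (female-biased) and 1 below (erythrocyte), each with an exact permutation p of 0.514 after adjustment over 36 lists.

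Of 130 tested small RNA genes, 103 had a positive and 27 a negative log2 fold change, with a median of 0.53, against -0.23 for 12930 other genes. Only Snord15a passed the threshold. Snord17 was at 8864 ± 4295 in the controls and 55501 ± 54285 in the mutants (SD, n = 4), and Rpph1, the RNA of RNase P, at 48433 ± 17327 and 32382 ± 10446, with limma adjusted p of 0.531 and 0.860.

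The 14 genes called were equalled or exceeded in 3 of the 35 splits of the 8 libraries into 4 and 4, the real one included, so chance is not excluded by this count. The highest other split called 3396 genes, and it is the one that parts the 4 libraries with the largest small RNA share from the rest, which points to a structure of the samples other than genotype. After median scaling, 1 of the 35 splits, the real one, gave 63 genes, and the highest other gave 4. This argues against chance for that count. Chance is not excluded, since 1 of 35 is the lowest possible outcome and the scaling was chosen after seeing the data. For gene lists, 2 of 35 splits gave the 19 lists of the preset-correlation test (highest other 19), and after median scaling 8 of 35 gave as many as the real 14 (highest other 20). Chance is therefore not excluded for the number of lists under either scaling.

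The first pattern is the median gene at -0.23, which was -0.03 without mutant 3487 and 0.23 without both mutants above 45% small RNA, so it rested on few libraries. With small RNA genes left out of the totals, the median log2 fold change was 0.0287 in place of -0.23, which is consistent with bases taken by small RNAs as its source. A loss of most transcripts with genotype cannot be told apart, because relative values carry no absolute amount, and the comparison of the median scale of the libraries between groups gave an exact permutation p of 0.429. Whether genotype raised the small RNA share itself is also open, since 2 of 4 mutants lay within the control range.

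The second pattern is the rise of female-biased genes. Female animals among the mutants are argued against, because the mutant library lowest in Y-linked genes still held 56.0% of the control mean. Scaling is argued against too, since the smallest log2 fold change of the 3 genes after median scaling was 2.09, above the widest gap of 1.23 between scale factors of any pair of libraries. A loss of androgen-dependent transcription may contribute, but the male-biased list had a camera adjusted p of 0.134 after median scaling. With the authors' scaling Kap, an abundant androgen-regulated gene, was at 48702 ± 6611 and 39424 ± 11925 (limma adjusted p = 0.906). After median scaling Kap was at 48847, 66941, 30053 and 37514 in controls 3401, 3486, 3586 and 3587. It was at 21381, 46596, 90494 and 32126 in mutants 3382, 3387, 3487 and 3489. A loss of androgen-dependent transcription therefore stays open. An effect of Mta2 loss or of injury on these genes is a hypothesis that was not tested.

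The third pattern is the higher level of macrophage and dendritic cell genes. After median scaling the list median was 1.18, still past the threshold of camera. With the authors' scaling it already lay 1.16 above the median gene. Median scaling divides all genes of a library by 1 factor, and camera compares a list with other genes. The result could therefore hardly differ, and it does not test scaling by small RNAs as the source. A lower share of tubule cells would raise other cell types alike, but the macrophage median exceeded the endothelial one by 1.47 (95% bootstrap interval over genes 1.12 to 1.67). That interval treats genes as independent and does not measure the spread between kidneys. By library, after median scaling, the macrophage score was above all controls in 4 of 4 mutants and the endothelial score below them in 4 of 4. With the authors' scaling it was 2 of 4 for each. The endothelial margin after median scaling was narrow, with mutant 3387 at 4.501 and control 3401 at 4.512. More immune cells in the mutant kidneys may be the source, as a hypothesis from the same data, and a change of expression within resident cells was not tested. The split count for lists above, and an adjusted p of 0.441 with an estimated correlation, limit this reading.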
